A study of Mus musculus with 16 samples.

How the data were processed

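RNA of mouse bone-marrow derived macrophages was hybridised to 1-colour Affymetrix mouse gene arrays, with 16 arrays in 6 groups of naive or pretreated cells at 0, 3 and 6 h. The deposited values are log2 intensities made by the authors, and biotin labelling followed the Affymetrix protocol, per the labels. Background correction, normalization and summary method are not given in the sources used here. The table holds 35557 features. Column medians lay between 7.151 and 7.226 in array set 1 and between 6.886 and 6.997 in set 2, and column minima between 2.842 and 2.939 and between 2.127 and 2.218, so the sets appear to have been normalized separately. Array sets were read from the numbering in the sample titles. No 2 arrays held identical values. For arrays the number of arrays limits the precision, here 2 per group and set.

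Gene symbols came from the platform annotation, which can be old. Of 35557 features 23410 are in it, 21789 with 1 symbol, 1621 with several and 12147 with none. Of the 21789, 21698 matched a current gene table by gene identifier and 91 did not, and no symbol changed. Features with several symbols were not named, so some genes, among them the interferon gene Gbp2 and H3f3b, which also encodes H3.3, are not analysed here. Of 999 genes with more than 1 feature the feature with the highest mean over all arrays was used, which gave 19938 genes.

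The values were used as deposited. A limma fit (version 3.58.1 in R 4.3.3) had 1 mean for each of 8 cells of group within array set, with 8 residual and 4.26 prior degrees of freedom, and every contrast was taken within a set, or averaged over both sets at 0 h. Fold changes are 2 to the power of the log2 change. Moderated limma p-values were adjusted by Benjamini-Hochberg over the 19938 genes of a comparison, and a gene counted as changed at an adjusted p under 0.05. Differences of responses were tested as contrasts in the same fit. Gene lists, 22 with 399 measured of 447 members, were written before the data were examined, as were the comparisons, their tests and all alternatives but array weights. The closing section names its tests chosen later. The lists cover interferon-inducible GTPases, chemokines, MHC class I and II, type I interferon-stimulated genes and JAK-STAT and IRF signalling. Others cover macrophage activation and identity, alternative activation, TLR and NF-kB genes, complement and cell cycle. The rest cover H3.3, histone chaperones and H3K36 methylation genes, cholesterol biosynthesis, heat shock and immediate early genes and markers of other cell types. Lists were tested with camera at a preset correlation of 0.01, adjusted over 220 list and comparison pairs, and again with an estimated correlation. List calls given without a second p held with it or are described by their members alone. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

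The rule for named genes was fixed before the data were examined: for each comparison the 10 largest rises and 10 largest falls past the threshold, with the arrays of the groups not overlapping within a set (no such condition for differences of responses), up to 4 members of each list with the largest absolute change, and a fixed set of interferon genes. The genes named in the text are a subset of those, picked after their values were seen. The exceptions are genes outside the rule that are named because a count is small. Of 394 gene and comparison pairs that the rule gives past the threshold, 246 (62.4%) kept the call with any 1 array left out, and of the 253 in the text 170 (67.2%) did, so the text holds somewhat more stable calls than the rule gives.

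The fit was tested on simulated data with 200 of 19938 genes changed. At a log2 change of 1 it recovered 74% for naive cells at 3 h, 76% at 6 h, 96% for pretreated against naive cells at 0 h, 83% at 3 h and 82% at 6 h, and 45% and 51% for the differences of responses at 3 h and 6 h. At a log2 change of 2 it recovered 95% or more in each of those, except 92% for the difference of responses at 6 h. False calls among the unchanged genes ranged from 4 for that difference to 15 for the difference at 3 h. Noise was drawn independently for each array, whereas deviations of real arrays correlated at up to 0.662. The recovered shares therefore hold for independent arrays only.

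Alternatives were an additive array-set term, no array-set term, the half-set as a block, each array set alone, a filter on dim features (mean log2 under 6.5, which left 13094 genes), all features, the mean of the features of a gene, quantile normalization again, eBayes with trend and robust, a 2-fold limit, camera with an estimated correlation, and each array left out. When an array left out leaves a group with 1 array in its set, the lone array is assumed to vary like the other groups. Array weights were added after the data were examined. The labels hold no replicate numbers that pair arrays across groups, so no pairing was used.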

Results

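Gene expression was measured in mouse macrophages grown from bone marrow in medium conditioned by L cells. The mice carried a knock-in of HA-tagged histone H3.3, a replacement histone that is deposited outside DNA replication. The macrophages were treated with interferon-gamma, the cytokine with which lymphocytes activate macrophages. Naive cells were sampled at 0 h (n = 4 arrays), 3 h (n = 2) and 6 h (n = 2). Cells called pretreated here, from a token in the sample titles that names earlier interferon, were sampled at 0 h (n = 4), 3 h (n = 2) and 6 h (n = 2). The dose and length of the pretreatment and any rest after it are not given in the sources used here. The 16 arrays came in 2 array sets of 8. Set 1 held 0 h and 6 h arrays, with replicates 1 and 2 of each 0 h group, and set 2 held 0 h and 3 h arrays, with replicates 3 and 4. Values are log2 intensities of 19938 genes. Each log2 change compares 2 arrays with 2 arrays of the same set, except where 4 arrays stand against 4. A difference of changes combines 8 arrays. The value after ± is the SE from 1 fit to all 16 arrays. A gene therefore has the same SE in every comparison of 2 with 2 arrays, and that SE also holds spread between arrays outside the comparison. The labels do not say whether replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

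Arrays of the same group and set correlated across genes at 0.9812 to 0.993, with a median of 0.9914, and the lowest pair was pretreated 0 h replicates 1 and 2. Genes are not independent replicates, so these values only describe likeness. After each array set was centred on its own mean, the first principal component held 49.6% of the variance and the second 12.3%. Naive 0 h arrays had first-component scores of -37.7 to -28.4 and pretreated 0 h arrays of -23.7 to -10.9. The scores were 17.0 and 19.7 in naive and 21.7 and 28.0 in pretreated cells at 3 h, and 42.4 and 36.6 in naive and 23.3 and 20.1 in pretreated cells at 6 h.

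**Figure D1:**
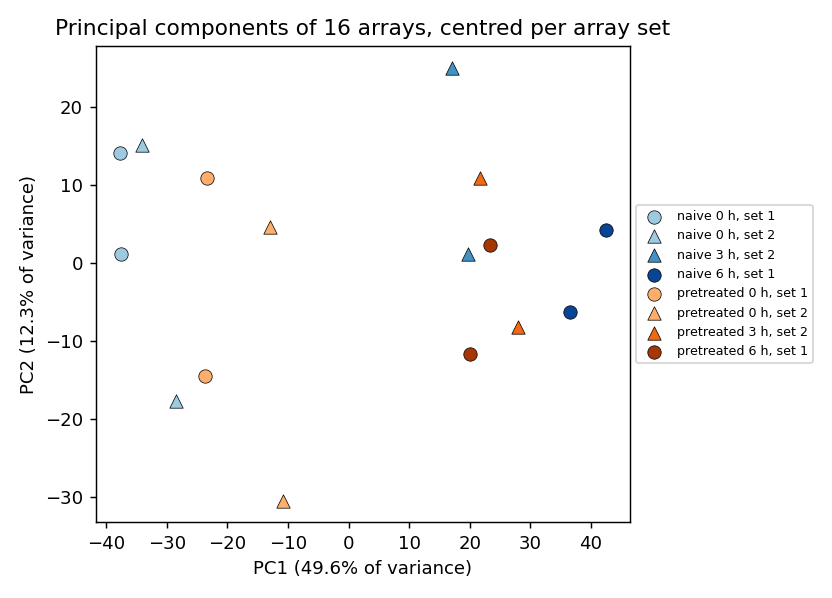
Scores of the 16 arrays on the first component (x axis, 49.6% of variance) and the second (y axis, 12.3%), after each array set was centred on its own mean. Each point is 1 array, colours mark group and time, circles set 1 and triangles set 2, and the 4 naive 0 h arrays lie farthest to the left.

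The first comparison asks which genes changed in naive cells after 3 h. No unstimulated cells were sampled at 3 h or 6 h. In every change from 0 h, interferon therefore cannot be told apart from time in culture or handling. Of 19938 genes, 671 rose and 417 fell. Cxcl9, a chemokine that attracts activated T cells through CXCR3, rose (log2 change 7.32 ± 0.17, adjusted p = 1.69e-10). Its level in naive cells at 0 h in the same set, 5.99, lay under the dim limit of 6.5, so no fold is given. Means of naive 0 h cells under that limit, in 1 set or both, were also found for Iigp1 (6.27), Gbp4 (5.44 and 6.41), Gbp2b, C1s1, C4b, Ccl8, Ch25h, Clec9a, Cysltr2, Klrk1, Nos2, Plac8, Rasgrp1, Sectm1a, Slamf8 and Xcr1. Their log2 differences, here and below, start from a level not shown to be above background, so their size is uncertain. The list of interferon-inducible GTPases has 20 genes, of which 10 were measured here and below. Another 9 lay only on features with several symbols and 1 was not matched. All 10 measured interferon-inducible GTPases, which attack vacuoles of intracellular pathogens, rose (10 adjusted over the list alone, median log2 change 3.84, camera adjusted p = 9.33e-30). Among them Iigp1 rose by 6.39 ± 0.27, Gbp4 by 6.15 ± 0.42 and Gbp5 by 5.5 ± 0.35. Of 33 type I interferon-stimulated antiviral genes 28 rose and none fell (31 adjusted over the list alone, median 1.37). Among them were the nucleic acid sensor Zbp1 at 3.4 ± 0.21, Ifit2 at 3.16 ± 0.2, Mx1 at 2.86 ± 0.49, Ifit1 at 2.56 ± 0.26 and Daxx, also an H3.3 chaperone, at 1.97 ± 0.17. Of 16 genes of MHC class I presentation 12 rose (13 adjusted over the list alone, median 0.99), among them the class I transactivator Nlrc5 at 2.35 ± 0.14 and the peptide transporter Tap1 at 1.97 ± 0.12.

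Of 21 JAK-STAT and IRF genes 12 rose and 2 fell at 3 h (14 and 3 adjusted over the list alone, median 0.95). Among them were Batf2 at 4.44 ± 0.18, the feedback inhibitors Socs1 at 4.25 ± 0.15 and Socs3 at 4.04 ± 0.21, and the transcription factor Irf1 at 2.93 ± 0.15. Of 29 macrophage activation genes 17 rose and none fell (19 adjusted over the list alone, median 0.94). They included Acod1, which makes itaconate, at 4.42 ± 0.28, the checkpoint ligand Cd274 at 3.79 ± 0.55, the Fc receptor Fcgr4 at 2.83 ± 0.2 and the nitric oxide synthase Nos2 at 2.24 ± 0.48. Of 16 chemokines 5 rose (6 adjusted over the list alone, where 2 also fell), among them Cxcl10 at 3.91 ± 0.28 and Ccl8 at 3.04 ± 0.31. Chemokine genes as a list had adjusted p = 0.0005, or adjusted p = 0.0965 with an estimated correlation. Outside the lists Sectm1a (5.02 ± 0.38), Ifi205 (4.67 ± 0.16), Slamf8 (4.63 ± 0.3) and Cd69 (4.48 ± 0.34) were among the 10 largest rises. The 10 largest falls included the sphingosine-1-phosphate receptor S1pr1 (-4.17 ± 0.18), Cd300lb (-2.78 ± 0.32), Rhob (-2.56 ± 0.36), Gpr183 (-2.38 ± 0.19) and the phosphatase Dusp1 (-2.36 ± 0.43). Of 9 MHC class II genes only H2-DMa rose (0.87 ± 0.19, 2 adjusted over the list alone), while H2-Aa (0.48 ± 1.38, adjusted p = 0.95) and the transactivator Ciita (1.62 ± 0.54, adjusted p = 0.127) did not pass.

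Smaller groups moved in parts at 3 h. Of 21 alternative activation genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Clec10a at 2.56 ± 0.42 and the interleukin 4 receptor Il4ra at 1.9 ± 0.12. Of 24 TLR and NF-kB genes 4 rose and 1 fell (4 and 3 adjusted over the list alone). Among them was the prostaglandin synthase Ptgs2 at 3.68 ± 0.5. TLR and NF-kB genes as a list had adjusted p = 0.0468, or adjusted p = 0.694 with an estimated correlation. Of 12 complement genes 4 rose and 1 fell in both adjustments. Complement genes as a list had adjusted p = 0.00669, or adjusted p = 0.177 with an estimated correlation. Of 22 heat shock and immediate early genes 2 rose and 2 fell in both adjustments, with the mRNA decay factor Zfp36 at 1.23 ± 0.14, Fos at -1.84 ± 0.33 and Dusp1 as above. Of 14 histone H3.3, chaperone and H3K36 methylation genes 2 rose and 1 fell (2 and 3 adjusted over the list alone), the fall being Chaf1a at -0.89 ± 0.23, and H3f3a, which encodes H3.3, was at -0.06 ± 0.15 (adjusted p = 0.934). The levels of H3f3a (5.89 to 6.61 over all groups) lay around the dim limit of 6.5, so its values here and below do not show whether H3.3 expression changed. Of 40 cell cycle genes only cyclin E2, Ccne2, fell (-1.37 ± 0.34), none passed when adjusted over the list alone, and the median was -0.47. Cell cycle genes as a list had adjusted p = 5.3e-10, or adjusted p = 0.253 with an estimated correlation. Of 23 macrophage identity genes 2 rose and 1 fell in both adjustments, the fall being the fractalkine receptor Cx3cr1 (-2.0 ± 0.31), and none of 18 cholesterol biosynthesis genes passed.

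The count of 1088 changed genes at 3 h was 716 without naive 0 h replicate 3, 660 without replicate 4, 663 without naive 3 h replicate 1 and 543 without replicate 2. Of the genes named at 3 h, Nos2 lost its call with any 1 of these 4 arrays left out (adjusted p up to 0.116, without naive 3 h replicate 2). H2-DMa lost it without naive 0 h replicate 3 or 4 or naive 3 h replicate 1 (up to 0.165), Ccne2 without naive 0 h replicate 4 or naive 3 h replicate 1 (up to 0.296), and Fos without naive 0 h replicate 4 or naive 3 h replicate 2 (up to 0.0712). Dusp1 lost it without naive 3 h replicate 2 (adjusted p = 0.0514), and Chaf1a without naive 0 h replicate 4 or either naive 3 h array (up to 0.301).

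After 6 h, naive cells showed 1492 genes that rose and 2161 that fell. Of the 671 genes that had risen at 3 h, 518 rose at 6 h on separate arrays, against 50.2 for independent lists, and of the 417 that had fallen 308 fell, against 45.2. Cxcl9 rose by 7.12 ± 0.17 (adjusted p = 2.36e-10). All 10 measured interferon-inducible GTPases rose (10 adjusted over the list alone, median 4.13), with Gbp4 at 6.56 ± 0.42 and Iigp1 at 5.47 ± 0.27. Of 16 MHC class I genes 15 rose in both adjustments (median 1.44), with Tapbpl at 2.42 ± 0.15, Nlrc5 at 2.26 ± 0.14 and Tap1 at 2.08 ± 0.12. Of 33 type I interferon-stimulated genes 29 rose (30 adjusted over the list alone, median 1.26). Among them were Zbp1 at 2.97 ± 0.21 and Ifit2 at 2.11 ± 0.2. Type I interferon-stimulated genes as a list had adjusted p = 7.15e-26, or adjusted p = 0.0528 with an estimated correlation. Of 21 JAK-STAT and IRF genes 14 rose (14, and 1 fall, adjusted over the list alone), with Socs1 at 3.56 ± 0.15 and Irf1 at 2.26 ± 0.15. Of 29 macrophage activation genes 21 rose (22 adjusted over the list alone). Among them were Acod1 at 4.48 ± 0.28, the cytokine Tnf at 4.19 ± 0.65, the costimulator Cd40 at 3.75 ± 0.32 and Nos2 at 2.64 ± 0.48.

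Inflammatory and complement genes were among those that rose at 6 h. Of 24 TLR and NF-kB genes 10 rose and 2 fell (13 and 2 adjusted over the list alone). Among them were Ptgs2 at 5.65 ± 0.5 and the NF-kB inhibitors Nfkbie at 2.77 ± 0.44 and Tnfaip3 at 2.74 ± 0.32. TLR and NF-kB genes as a list had adjusted p = 0.000176, or adjusted p = 0.38 with an estimated correlation. Of 16 chemokines 7 rose and 2 fell in both adjustments, with Cxcl10 at 4.75 ± 0.28 and Cxcl11 at 4.61 ± 0.33. Chemokine genes as a list had adjusted p = 0.00109, or adjusted p = 0.114 with an estimated correlation. Of 12 complement genes 5 rose and 2 fell in both adjustments, with factor B, Cfb, at 3.87 ± 0.26, C1s1 at 2.82 ± 0.2 and C4b at 2.38 ± 0.23. Complement genes as a list had adjusted p = 0.00171, or adjusted p = 0.128 with an estimated correlation. Of 9 MHC class II genes 3 rose (5 adjusted over the list alone, median 2.06). Among them were Ciita at 3.35 ± 0.54 and H2-Ab1 at 2.92 ± 0.9, while H2-Aa (2.54 ± 1.38, adjusted p = 0.281) and the invariant chain Cd74 (2.27 ± 0.96, adjusted p = 0.14) did not pass. The SE of H2-Aa also holds the spread of naive cells in set 2 (SD 3.09 at 0 h and 2.94 at 3 h). In the naive 0 h and 6 h arrays of set 1 its SD was 1.26 and 1.02. MHC class II genes as a list had adjusted p = 0.000593, or adjusted p = 0.257 with an estimated correlation. Of 22 heat shock and immediate early genes 9 rose and 1 fell (10 and 2 adjusted over the list alone). Among them was the chaperone Hspa1a at 1.01 ± 0.16. Heat shock and immediate early genes as a list had adjusted p = 0.000292, or adjusted p = 0.0937 with an estimated correlation. Outside the lists Cnn3 (5.53 ± 0.41), Ch25h, which makes 25-hydroxycholesterol (5.09 ± 1.08), and uridine phosphorylase Upp1 (4.88 ± 0.27) were among the 10 largest rises.

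Of 40 cell cycle genes 28 fell and 1 rose at 6 h (31 and 2 adjusted over the list alone, median -1.67). The list had adjusted p = 1.62e-19, or adjusted p = 0.0965 with an estimated correlation. Among them were the mitotic kinesins Kif20a at -3.02 ± 0.2 and Kif11 at -2.66 ± 0.23, the spindle checkpoint kinase Bub1 at -2.82 ± 0.26 and cyclin A2, Ccna2, at -2.67 ± 0.19. Of 14 H3.3, chaperone and H3K36 methylation genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), the falls including the histone chaperones Asf1b (-2.05 ± 0.17) and Chaf1b (-1.61 ± 0.26), and H3f3a was at -0.07 ± 0.15 (adjusted p = 0.88). The iron exporter Slc40a1 (-4.39 ± 0.32), S1pr1 (-4.3 ± 0.18), Abcd2 (-3.55 ± 0.41) and the prostaglandin dehydrogenase Hpgd (-3.14 ± 0.5) were among the 10 largest falls. Of 21 alternative activation genes 6 rose and 3 fell (6 and 4 adjusted over the list alone), with the receptor Flt1 at 2.74 ± 0.2. Of 23 macrophage identity genes 2 rose and 2 fell in both adjustments, with Cebpb at 1.29 ± 0.19 and Cx3cr1 at -1.95 ± 0.31. Of 18 cholesterol biosynthesis genes 2 fell in both adjustments, with Dhcr7 at -0.69 ± 0.19, and the median was 0.15.

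The count of 3653 at 6 h was 2323 without naive 0 h replicate 2 and 2217 without naive 6 h replicate 1. H2-Ab1 lost its call with any 1 of the 4 arrays left out (adjusted p up to 0.259, without naive 6 h replicate 1), and Dhcr7 without naive 0 h replicate 1 or either naive 6 h array (up to 0.213).

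Whether the response of naive cells differed between 3 h and 6 h was tested as a difference of the changes, each within its own array set. All 3 h arrays lie in set 2 and all 6 h arrays in set 1, so time cannot be told apart from array set in this difference, and 0 h levels differed between sets (naive Asf1b 10.69 in set 1 and 12.12 in set 2). The 6 h minus 3 h difference of log2 changes passed for 136 genes with a positive and 209 with a negative sign, and a negative sign can be a deeper fall at 6 h. It was positive for the adenylate kinase Ak4 (4.6 ± 0.84, adjusted p = 0.0195), the lectin Clec9a (3.53 ± 0.56), Mthfd2 (2.46 ± 0.47), Procr (2.46 ± 0.53), Clec5a (2.43 ± 0.54), Upp1 (2.43 ± 0.38), Flt1 (2.37 ± 0.29), Cfb (2.28 ± 0.37), Il12rb1 (1.83 ± 0.3), C1s1 (1.73 ± 0.28), Il27 (1.58 ± 0.31), Hsp90aa1 (1.35 ± 0.29), Dnajb1 (1.15 ± 0.21), C1ra (1.0 ± 0.2) and the immunoproteasome subunit Psmb8 (0.93 ± 0.19). It was negative for Slc40a1, whose fall was deeper at 6 h (-3.69 ± 0.45), Ednrb (-2.69 ± 0.45), Arhgap19 (-2.66 ± 0.25), the aryl hydrocarbon receptor Ahr (-2.57 ± 0.55), Asf1b (-1.46 ± 0.24) and Cish (-1.38 ± 0.24). Of 40 cell cycle genes 16 were lower and 1 higher (24 and 3 adjusted over the list alone, median -1.1). Among them were Kif20a at -2.4 ± 0.28, Ccna2 at -2.32 ± 0.26 and Nusap1 at -2.31 ± 0.31. Cell cycle genes as a list had adjusted p = 4.61e-15, or adjusted p = 0.142 with an estimated correlation. Cxcl9 (-0.2 ± 0.24, adjusted p = 0.871), Irf1 (-0.67 ± 0.21, adjusted p = 0.153) and Tnf (2.82 ± 0.92, adjusted p = 0.171) did not pass.

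This count of 345 was 214 without naive 0 h replicate 1, 104 without replicate 2, 102 without replicate 4, 159 without naive 3 h replicate 1, 63 without naive 3 h replicate 2 and 134 without naive 6 h replicate 1. Of the genes named for it, Clec9a, Flt1, Cfb, Slc40a1, Kif20a, Ccna2, Nusap1 and Arhgap19 passed with any of the 8 arrays left out. Upp1 (adjusted p = 0.0535) and C1s1 (0.0578) lost the call without naive 3 h replicate 2, and Asf1b without it (0.0622) or without naive 0 h replicate 2 (0.0601). The others lost it for 3 to 7 of the 8 arrays, with adjusted p up to 0.0808 for Ak4 without naive 3 h replicate 1, up to 0.196 for Clec5a and 0.174 for Ahr without naive 0 h replicate 4, and up to 0.161 for Procr without naive 0 h replicate 2. For Hsp90aa1 (0.172), Mthfd2 (0.113), Psmb8 (0.148), Il27 without naive 3 h replicate 2 (0.114), C1ra without naive 0 h replicate 2 (0.12), Dnajb1 (0.102), Cish (0.085), Ednrb (0.0667) and Il12rb1 (0.0608) the largest adjusted p is given, without naive 0 h replicate 4 where no other array is named.

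What the pretreatment left before new stimulation was asked at 0 h, with 4 pretreated against 4 naive arrays over both sets. Of 19938 genes 161 were higher and 31 lower in pretreated cells. Cxcl9 was higher (5.59 ± 0.12, adjusted p = 6.58e-11), with levels of 11.6 ± 0.17 and 12.11 ± 0.27 (SD, n = 2 in each set) against 6.55 ± 0.36 and 5.99 ± 0.01 in naive cells, near or under the dim limit. All 10 measured interferon-inducible GTPases were higher in both adjustments (median 1.77), with Gbp4 at 4.61 ± 0.29 and Iigp1 at 4.21 ± 0.19. Of 16 MHC class I genes 15 were higher in both adjustments (median 0.95). Among them were Tap1 at 1.48 ± 0.08, H2-Q4 at 1.42 ± 0.14, Tapbpl at 1.25 ± 0.11 and Nlrc5 at 1.18 ± 0.1. Of 9 MHC class II genes 3 were higher and 9 when adjusted over the list alone (median 1.62). Among them were H2-Ab1 at 3.31 ± 0.64 and H2-Eb1 at 2.66 ± 0.49, while H2-Aa (3.88 ± 0.97, adjusted p = 0.11), Cd74 (2.85 ± 0.68, adjusted p = 0.084) and Ciita (1.24 ± 0.38, adjusted p = 0.245) did not pass over all genes. Of 33 type I interferon-stimulated genes 20 were higher (30 adjusted over the list alone, median 0.72). Among them were Zbp1 at 2.5 ± 0.15, Oasl1 at 1.75 ± 0.29, Mx1 at 1.65 ± 0.35, Ifit2 at 1.62 ± 0.14 and Ifit1 at 1.02 ± 0.18. Of 16 chemokines 4 were higher (5 adjusted over the list alone), among them Ccl5 (2.64 ± 0.28), Ccl8 (2.33 ± 0.22) and Cxcl10 (1.68 ± 0.19).

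Of 21 JAK-STAT and IRF genes 5 were higher at 0 h (9 adjusted over the list alone). Among them were Irf7 at 1.54 ± 0.14, Irf1 at 1.11 ± 0.1, Stat2 at 0.9 ± 0.08 and Socs1 at 0.54 ± 0.11. Of 29 macrophage activation genes 7 were higher (13 adjusted over the list alone). Among them were Acod1 at 2.57 ± 0.2, Fcgr4 at 1.81 ± 0.14 and the costimulator Cd86 at 1.47 ± 0.17, whereas Nos2 was at 0.35 ± 0.34 (adjusted p = 0.9). Of 12 complement genes 3 were higher in both adjustments, with Cfb at 1.74 ± 0.19 and C4b at 1.07 ± 0.16. Ifi213 (2.88 ± 0.22) and Slamf8 (2.77 ± 0.22) were among the 10 largest rises. Lower were the carbonyl reductase Cbr2 (-1.88 ± 0.13), the endothelin receptor Ednrb (-1.47 ± 0.23), Bmp2 (-0.94 ± 0.16), Igf1r (-0.93 ± 0.12), Colec12 (-0.81 ± 0.12) and the scavenger receptor Cd163 (-0.67 ± 0.12). Of 21 alternative activation genes 1 was higher and 1, Cd163, lower (1 and 2 adjusted over the list alone). No gene passed among 24 TLR and NF-kB (2 higher and 1 lower adjusted over the list alone), 40 cell cycle, 18 cholesterol biosynthesis, 22 heat shock and immediate early (1 lower adjusted over the list alone), 23 macrophage identity and 14 H3.3 and chaperone genes (1 higher and 1 lower adjusted over the list alone). H3f3a was at -0.08 ± 0.1 (adjusted p = 0.945). The cell cycle list, with a median of 0.22, had adjusted p = 1.19e-06, or adjusted p = 0.387 with an estimated correlation, and the cholesterol list, with a median of -0.33, had adjusted p = 6.56e-05, or adjusted p = 0.586 with an estimated correlation.

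Within set 1 alone the 0 h contrast held 45 genes higher and 9 lower, and within set 2 alone 88 and 5, with 39 higher in both, against 0.2 for independent lists. The difference between the sets passed for 1 gene. Of the 45 genes higher in set 1, 39 rose in naive cells at 3 h on set 2 (1.5 for independent lists), and of the 88 higher in set 2, 85 rose at 6 h on set 1 (6.6). H2-Ab1 lost its 0 h call without naive replicate 2 or 4 or pretreated replicate 1, 2 or 3 (adjusted p up to 0.134, without naive replicate 2), and H2-Eb1 without the same arrays (up to 0.105). Mx1 lost it for 7 of the 8 arrays, all but naive replicate 4 (up to 0.205, without naive replicate 3). Ifit1 lost it without naive replicate 1, 2 or 3 or pretreated replicate 1 or 3 (up to 0.0794), and Socs1 without naive replicate 1, 2 or 3 or pretreated replicate 1, 3 or 4 (up to 0.147). Cd163 lost it without naive replicate 2 or 4 or pretreated replicate 1, 3 or 4 (up to 0.111), and Bmp2 without naive replicate 4 or pretreated replicate 1, 3 or 4 (up to 0.0667).

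**Figure D2:**
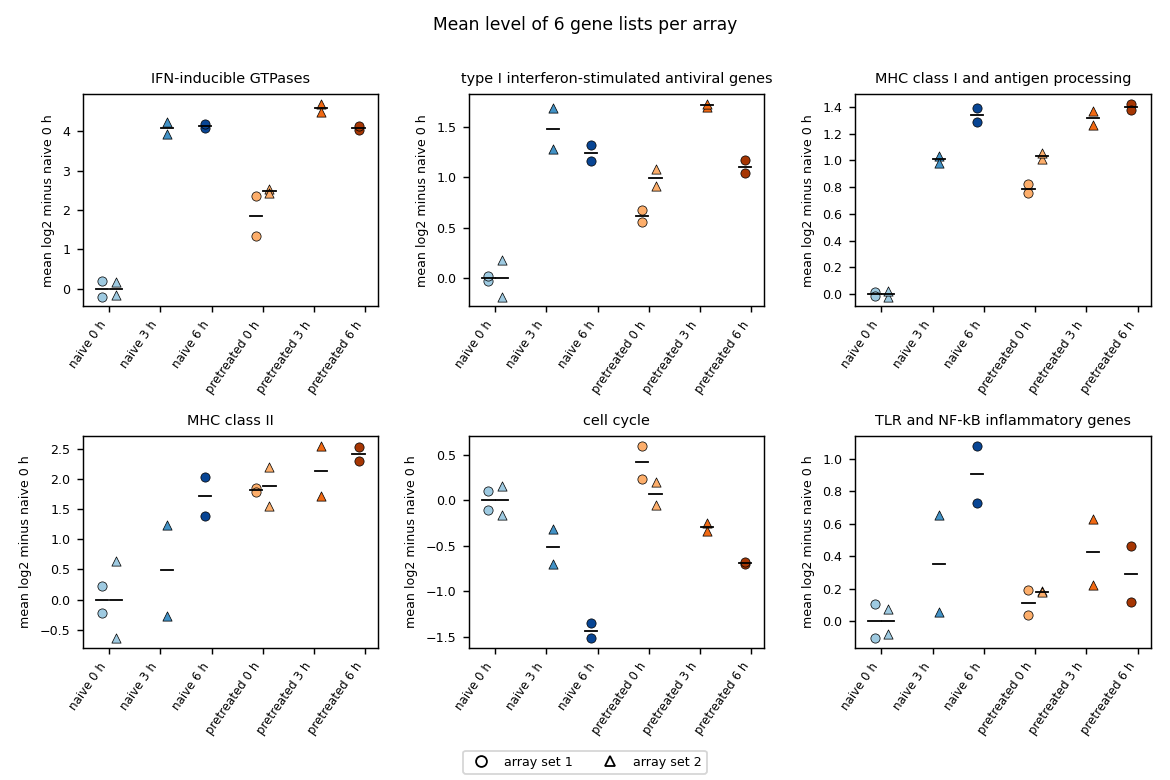
Mean log2 level of 6 gene lists per array (y axis), minus the mean of the naive 0 h arrays of the same set, by group and time (x axis). Points are arrays, circles set 1 and triangles set 2, bars are the mean of 2 arrays, and the pretreated 0 h mean of the interferon-inducible GTPases lay between naive 0 h and the stimulated groups in each set.

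Pretreated cells were stimulated again, and their change was taken against their own 0 h level. At 3 h 370 genes rose and 199 fell, and 348 of the rises and 182 of the falls were also called in naive cells on separate arrays, against 12.5 and 4.2 for independent lists. Ptgs2 (3.77 ± 0.5), Sectm1a (3.56 ± 0.38), the receptor Klrk1 (3.45 ± 0.4), Upp1 (3.44 ± 0.27), Batf2 (3.37 ± 0.18), Gbp11 (3.32 ± 0.35), Socs1 (3.3 ± 0.15), Nos2 (3.21 ± 0.48) and the collagenase Mmp13 (3.19 ± 0.25) were among the 10 largest rises. All 10 measured interferon-inducible GTPases rose in both adjustments (median 2.01), with Gbp5 at 2.96 ± 0.35. Of 33 type I interferon-stimulated genes 13 rose (25 adjusted over the list alone). Among them was Ifit2 at 1.35 ± 0.2, whereas Mx1 (1.66 ± 0.49, adjusted p = 0.112) did not pass. Type I interferon-stimulated genes as a list had adjusted p = 5.08e-25, or adjusted p = 0.0547 with an estimated correlation. Of 29 macrophage activation genes 12 rose (18 adjusted over the list alone). Among them was Cd40 at 2.37 ± 0.32. Of 21 JAK-STAT and IRF genes 8 rose and 1 fell (12 and 3 adjusted over the list alone), with Irf1 at 1.28 ± 0.15. Of 16 MHC class I genes 3 rose (5 adjusted over the list alone). Among them were Nlrc5 at 0.88 ± 0.14 and Tap1 at 0.5 ± 0.12. MHC class I genes as a list had adjusted p = 7.98e-06, or adjusted p = 0.0528 with an estimated correlation. Of 16 chemokines 3 rose and 1 fell (4 and 2 adjusted over the list alone). Among them were Cxcl11 at 3.08 ± 0.33, Cxcl10 at 1.88 ± 0.28, Cxcl9 at 1.25 ± 0.17 and the neutrophil chemokine Cxcl2 at -1.76 ± 0.43. Of 24 TLR and NF-kB genes 4 rose and 2 fell in both adjustments, with Il1rn, the interleukin 1 receptor antagonist, at 1.9 ± 0.2. S1pr1 (-3.35 ± 0.18), Rasgrp3 (-2.22 ± 0.32), Gpr183 (-1.93 ± 0.19) and Smad3 (-1.8 ± 0.18) were among the 10 largest falls, and Cx3cr1 fell too (-1.66 ± 0.31). Ciita (1.73 ± 0.54, adjusted p = 0.132) did not pass, nor did any of 9 MHC class II or 40 cell cycle genes.

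The count of 569 was 219 without pretreated 0 h replicate 4, 321 without pretreated 3 h replicate 1 and 242 without pretreated 3 h replicate 2. Tap1 lost its call with any 1 of the 4 arrays left out (adjusted p up to 0.181, without pretreated 0 h replicate 4), Cxcl2 without either pretreated 0 h array or pretreated 3 h replicate 2 (up to 0.43), and Cx3cr1 without pretreated 0 h replicate 4 or either pretreated 3 h array (up to 0.104).

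At 6 h 576 genes rose and 550 fell in pretreated cells, 503 and 515 of them also called in naive cells on separate arrays, against 43.1 and 59.6 for independent lists. Upp1 (4.51 ± 0.27), Cnn3 (4.42 ± 0.41), Ptgs2 (4.04 ± 0.5), Klrk1 (3.94 ± 0.4) and Clec9a (3.62 ± 0.39) were among the 10 largest rises. All 10 measured interferon-inducible GTPases rose in both adjustments (median 1.85), with Gbp2b at 3.32 ± 0.4. Of 16 MHC class I genes 9 rose (12 adjusted over the list alone), with Tapbpl at 1.42 ± 0.15. Of 21 JAK-STAT and IRF genes 11 rose and 1 fell (14 and 1 adjusted over the list alone). Among them were Batf2 at 3.28 ± 0.18, Socs1 at 3.19 ± 0.15 and Irf1 at 1.43 ± 0.15. Of 33 type I interferon-stimulated genes 11 rose (16 adjusted over the list alone), while Mx1 (1.31 ± 0.49, adjusted p = 0.191) did not pass. Type I interferon-stimulated genes as a list had adjusted p = 2.78e-15, or adjusted p = 0.131 with an estimated correlation. Of 29 macrophage activation genes 11 rose (13 adjusted over the list alone). Among them was Il12rb1 at 2.74 ± 0.21, while Nos2 (1.57 ± 0.48, adjusted p = 0.0904) and Cd274 (1.98 ± 0.55, adjusted p = 0.059) did not pass. Of 16 chemokines 4 rose and 3 fell (5 and 4 adjusted over the list alone), with Cxcl10 at 2.99 ± 0.28, Cxcl9 at 1.9 ± 0.17 and Cxcl2 at -1.68 ± 0.43. Of 9 MHC class II genes 2 rose in both adjustments, Ciita at 2.79 ± 0.54 and H2-DMa at 1.1 ± 0.19. MHC class II genes as a list had adjusted p = 0.023, or adjusted p = 0.479 with an estimated correlation. Of 40 cell cycle genes 25 fell and none rose (26 adjusted over the list alone, median -1.19). Among them were Prc1 at -2.19 ± 0.21, Bub1 at -2.14 ± 0.26 and Kif11 at -1.91 ± 0.23. Cell cycle genes as a list had adjusted p = 7.19e-27, or adjusted p = 0.0528 with an estimated correlation. S1pr1 (-3.79 ± 0.18), Slc40a1 (-3.46 ± 0.32), Cx3cr1 (-2.8 ± 0.31) and the DNA glycosylase Neil3 (-2.15 ± 0.24) were among the 10 largest falls, and Asf1b fell by 1.52 ± 0.17.

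The count of 1126 was 725 without pretreated 0 h replicate 2, 486 without pretreated 6 h replicate 1 and 514 without pretreated 6 h replicate 2. Cxcl2 lost its call with any 1 of the 4 arrays left out (adjusted p up to 0.237, without pretreated 6 h replicate 2), and Ciita without pretreated 0 h replicate 1 or either pretreated 6 h array (up to 0.0689).

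Whether the change from 0 h differed with pretreatment was tested as the difference between the 2 changes. A higher 0 h level alone makes this difference negative where both groups reach the same level. At 3 h pretreated and naive cells reached 13.36 and 13.3 for Cxcl9, and 12.89 and 13.04 for Irf1. At 3 h 16 genes passed, all with a smaller change in pretreated cells. The difference was -6.07 ± 0.24 for Cxcl9 (adjusted p = 1.09e-07), -4.48 ± 0.38 for Iigp1, -2.77 ± 0.23 for Ifi205, -2.76 ± 0.39 for Acod1, -2.61 ± 0.29 for Zbp1, -2.3 ± 0.36 for Gbp3, -1.94 ± 0.28 for Fcgr4, -1.82 ± 0.29 for Ifit2 and -1.65 ± 0.21 for Irf1. Among MHC class I genes it passed for Tap1 and Nlrc5 (-1.47 ± 0.17 and -1.47 ± 0.2), Tapbpl (-1.32 ± 0.21) and Psmb9 (-1.09 ± 0.14), 4 of 16 and 11 when adjusted over the list alone (median -0.76). Of the interferon-inducible GTPases 2 of 10 passed (7 adjusted over the list alone, median -1.62), with Gbp4 at -3.62 ± 0.59 (adjusted p = 0.0526), and of 33 type I interferon-stimulated genes 2 (18 adjusted over the list alone, median -0.72). Cxcl10 (-2.03 ± 0.39, adjusted p = 0.156) and Socs1 (-0.95 ± 0.21, adjusted p = 0.316) did not pass.

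At 6 h the difference of responses passed for 23 genes with a negative and 6 with a positive sign (pretreated minus naive). With the half-sets as a block 1095 genes passed at 6 h and 13 at 3 h, and with an additive array-set term alone 245 and 10. The values below come from the main fit. The difference of 6 h responses is meant where no other is named. It was -5.22 ± 0.24 for Cxcl9 (adjusted p = 6.65e-07), -4.16 ± 0.59 for Gbp4, -3.78 ± 0.38 for Iigp1, -2.77 ± 0.39 for Acod1, -2.55 ± 0.37 for Cfb, -2.53 ± 0.43 for Slamf8, -2.47 ± 0.25 for Rasgrp1, -2.07 ± 0.28 for C1s1, -1.74 ± 0.29 for Zbp1 and -1.38 ± 0.17 for Tap1. It was positive for the prostaglandin receptor Ptger1 (1.43 ± 0.18), the checkpoint receptor Havcr2 (1.3 ± 0.22) and Lpxn (1.14 ± 0.18). Of the interferon-inducible GTPases 2 of 10 passed (8 adjusted over the list alone, median -1.62). Interferon-inducible GTPase genes as a list had adjusted p = 7.97e-16, or adjusted p = 0.0528 with an estimated correlation. Of 16 MHC class I genes 2 passed (12 adjusted over the list alone, median -0.87), and of 33 type I interferon-stimulated genes 1 (18 adjusted over the list alone, median -0.7), the latter list with adjusted p = 5.85e-23, or adjusted p = 0.0622 with an estimated correlation. Irf1 (-0.84 ± 0.21, adjusted p = 0.182), Socs1 (-0.37 ± 0.21, adjusted p = 0.68) and Kif20a (1.23 ± 0.28, adjusted p = 0.147) did not pass.

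The 16 genes at 3 h were 10 without naive 3 h replicate 2 or without pretreated 3 h replicate 1, 9 without pretreated 0 h replicate 4 and 8 without pretreated 3 h replicate 2. Cxcl9, Iigp1, Ifi205, Zbp1 and Tap1 passed at 3 h with any of the 8 arrays left out. Irf1 lost its call without naive 3 h replicate 2, pretreated 0 h replicate 4 or pretreated 3 h replicate 2 (adjusted p up to 0.0639), and Psmb9 without naive 0 h replicate 4, naive 3 h replicate 1, pretreated 0 h replicate 4 or pretreated 3 h replicate 2 (up to 0.0803). Acod1 lost it for 6 of the 8 arrays (up to 0.128) and Gbp3 (0.31), Fcgr4 (0.13), Nlrc5 (0.103), Tapbpl (0.31) and Ifit2 (0.31) for 7, each with the largest adjusted p without pretreated 3 h replicate 2. The 29 genes at 6 h were 18 without naive 0 h replicate 1, 5 without naive 0 h replicate 2, 9 without pretreated 0 h replicate 2, 4 without naive 6 h replicate 1, pretreated 6 h replicate 1 or pretreated 6 h replicate 2, and 157 without naive 6 h replicate 2. Cxcl9, Iigp1 and Rasgrp1 passed at 6 h with any of the 8 arrays left out. Gbp4 (0.108), Slamf8 (0.284), Tap1 (0.0721), Zbp1 (0.214), Ptger1 (0.0791), Havcr2 (0.298) and Lpxn (0.172) lost their calls for 3 to 8 arrays, with the largest adjusted p without pretreated 6 h replicate 2. Acod1 (0.115) and Cfb (0.124) lost theirs with the largest adjusted p without pretreated 0 h replicate 2, and C1s1 (0.0887) without pretreated 6 h replicate 1.

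Genes can also be picked on one array set and read on the other, which keeps the noise of the picking arrays out of the value. Genes picked for a rise were picked in naive cells and not in pretreated cells, which can favour a larger naive change. The 671 genes that rose in naive cells at 3 h changed at 6 h by a median of 1.04 in naive and 0.57 in pretreated cells, and their difference of responses had a median of -0.44 (camera p = 1.2e-43, p = 7.43e-05 with an estimated correlation). The 1492 genes that rose at 6 h changed at 3 h by a median of 0.39 in naive and 0.27 in pretreated cells, with a difference of -0.13 (camera p = 6.11e-24, p = 0.0199 with an estimated correlation). That difference was -0.055 without pretreated 0 h replicate 4, -0.077 without pretreated 3 h replicate 2 and -0.225 without pretreated 0 h replicate 3. The 45 genes higher in pretreated cells at 0 h in set 1 had a median difference of 3 h responses of -1.1 in set 2, and the 88 higher in set 2 had -0.93 at 6 h in set 1.

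The level reached after stimulation was compared between pretreated and naive cells directly. With the half-sets as a block 88 genes passed at 3 h and 1098 at 6 h. The calls below come from the fit without that block. At 3 h 3 genes passed, Aif1, also called IBA1 (1.48 ± 0.19, adjusted p = 0.0387), the class I gene H2-Q5 (1.05 ± 0.14, adjusted p = 0.0407) and Cbr2 (-2.45 ± 0.19, adjusted p = 0.000264), and 738 genes had an unadjusted limma p under 0.05. Cxcl9 (0.05 ± 0.17), Irf1 (-0.15 ± 0.15) and Gbp4 (1.4 ± 0.42, adjusted p = 0.882) did not pass. None of 9 MHC class II genes passed over all genes and 7 were higher when adjusted over the list alone (median 1.27. MHC class II genes as a list had adjusted p = 7.2e-12, or adjusted p = 0.0381 with an estimated correlation), with H2-Aa at 3.74 ± 1.38, H2-Ab1 at 3.04 ± 0.9, Cd74 at 2.57 ± 0.96 and H2-Eb1 at 2.49 ± 0.7. In naive cells of set 2 the 2 arrays of H2-Aa lay far apart, at 7.33 ± 3.09 at 0 h and 7.81 ± 2.94 at 3 h (SD, n = 2). Of 16 MHC class I genes 8 were higher when adjusted over the list alone and none over all genes (median 0.26), with H2-Q4 at 0.75 ± 0.2 and H2-M3 at 0.69 ± 0.17. The count of 3 was 2 without naive 3 h replicate 2 and 1 without naive 3 h replicate 1 or either pretreated 3 h array. Aif1 and H2-Q5 lost their calls without each of the 4, with adjusted p up to 0.516 for Aif1 without pretreated 3 h replicate 1 and up to 0.539 for H2-Q5 without naive 3 h replicate 2.

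At 6 h 86 genes were higher and 54 lower in pretreated than in naive cells. Of 40 cell cycle genes 6 were higher and none lower (26 higher adjusted over the list alone, median 0.71). The 6 included Kif20a at 1.37 ± 0.2, Mcm7 of the replicative helicase at 1.31 ± 0.25 and the mitotic kinase Plk1 at 1.27 ± 0.15. Rrm2, at 1.22 ± 0.26 (adjusted p = 0.0566), did not pass over all genes. The cell cycle list had adjusted p = 3.19e-24, or adjusted p = 0.0603 with an estimated correlation. Asf1b was higher (1.14 ± 0.17), as were Inpp5j (1.81 ± 0.28), Plac8 (1.63 ± 0.17), Slamf9 (1.62 ± 0.29), Havcr2 (1.48 ± 0.16), the phosphatase Ptpn22 (1.45 ± 0.24), Cysltr2 (1.38 ± 0.28) and Ccl6 (0.67 ± 0.11). Lower were the transcription factor Egr2 (-2.45 ± 0.43), Cxcl2 (-2.38 ± 0.43), the lectin Clec4e (-2.36 ± 0.33), Rasgrp1 (-2.08 ± 0.17), the gap junction gene Gja1 (-2.04 ± 0.38), Cxcl11 (-2.01 ± 0.33), C1s1 (-1.88 ± 0.2), Procr (-1.87 ± 0.37), Trim13 (-1.79 ± 0.18), Lpar1 (-1.74 ± 0.21), Socs3 (-1.39 ± 0.21) and Ier3 (-1.32 ± 0.2). Of 24 TLR and NF-kB genes 2 were lower (12 lower and 1 higher adjusted over the list alone, median -0.49). TLR and NF-kB genes as a list had adjusted p = 5.38e-09, or adjusted p = 0.142 with an estimated correlation, while Tnf (-1.65 ± 0.65, adjusted p = 0.303) and Ptgs2 (-1.4 ± 0.5, adjusted p = 0.24) did not pass. None of 29 macrophage activation genes passed over all genes (1 higher and 4 lower adjusted over the list alone), with Vcam1 at -2.07 ± 0.52 and Gch1 at -1.45 ± 0.33. Macrophage activation genes as a list had adjusted p = 5.4e-06, or adjusted p = 0.15 with an estimated correlation. Among lists without a call, cholesterol biosynthesis had a median of -0.6 (Idi1 -1.92 ± 0.58, Cyp51 -1.61 ± 0.59) and adjusted p = 0.000341, or adjusted p = 0.634 with an estimated correlation, and MHC class II had a median of 0.65, with H2-Eb1 at 1.46 ± 0.7, and adjusted p = 0.00725, or adjusted p = 0.387 with an estimated correlation. Hspa1a (-0.76 ± 0.16, adjusted p = 0.0595), H3f3a (-0.26 ± 0.15, adjusted p = 0.564), Cxcl9 (-0.17 ± 0.17) and Irf1 (-0.11 ± 0.15) did not pass.

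This count of 140 was 18 without naive 6 h replicate 1, 406 without naive 6 h replicate 2, 22 without pretreated 6 h replicate 1 and 13 without pretreated 6 h replicate 2. Plac8, Havcr2, Plk1, Rasgrp1, C1s1 and Trim13 passed with any of these 4 left out. The other genes named as higher or lower lost their calls without at least 2 of the 4, with pretreated 6 h replicate 2 among them for each. Without that replicate the adjusted p was 0.138 for Inpp5j, 0.291 for Slamf9, 0.169 for Kif20a, 0.169 for Mcm7, 0.128 for Asf1b, 0.276 for Egr2, 0.295 for Cxcl2, 0.169 for Clec4e, 0.26 for Cxcl11, 0.0501 for Lpar1, 0.199 for Socs3, 0.0767 for Ier3, 0.291 for Ptpn22, 0.335 for Cysltr2, 0.379 for Procr, 0.338 for Gja1 and 0.257 for Ccl6. Inpp5j, Slamf9, Kif20a, Mcm7, Egr2, Cxcl2, Clec4e, Cxcl11, Socs3, Ier3, Ptpn22, Cysltr2, Procr, Gja1 and Ccl6 also lost theirs without naive 6 h replicate 1, with adjusted p from 0.0522 for Kif20a to 0.31 for Cysltr2 and Gja1. Without pretreated 6 h replicate 1 the calls of all these genes but Kif20a, Clec4e and Cxcl11 were lost, with adjusted p from 0.0504 for Lpar1 to 0.262 for Mcm7. Slamf9 (0.0593), Mcm7 (0.0714) and Cysltr2 (0.0774) lost theirs without naive 6 h replicate 2 too.

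**Figure D3:**
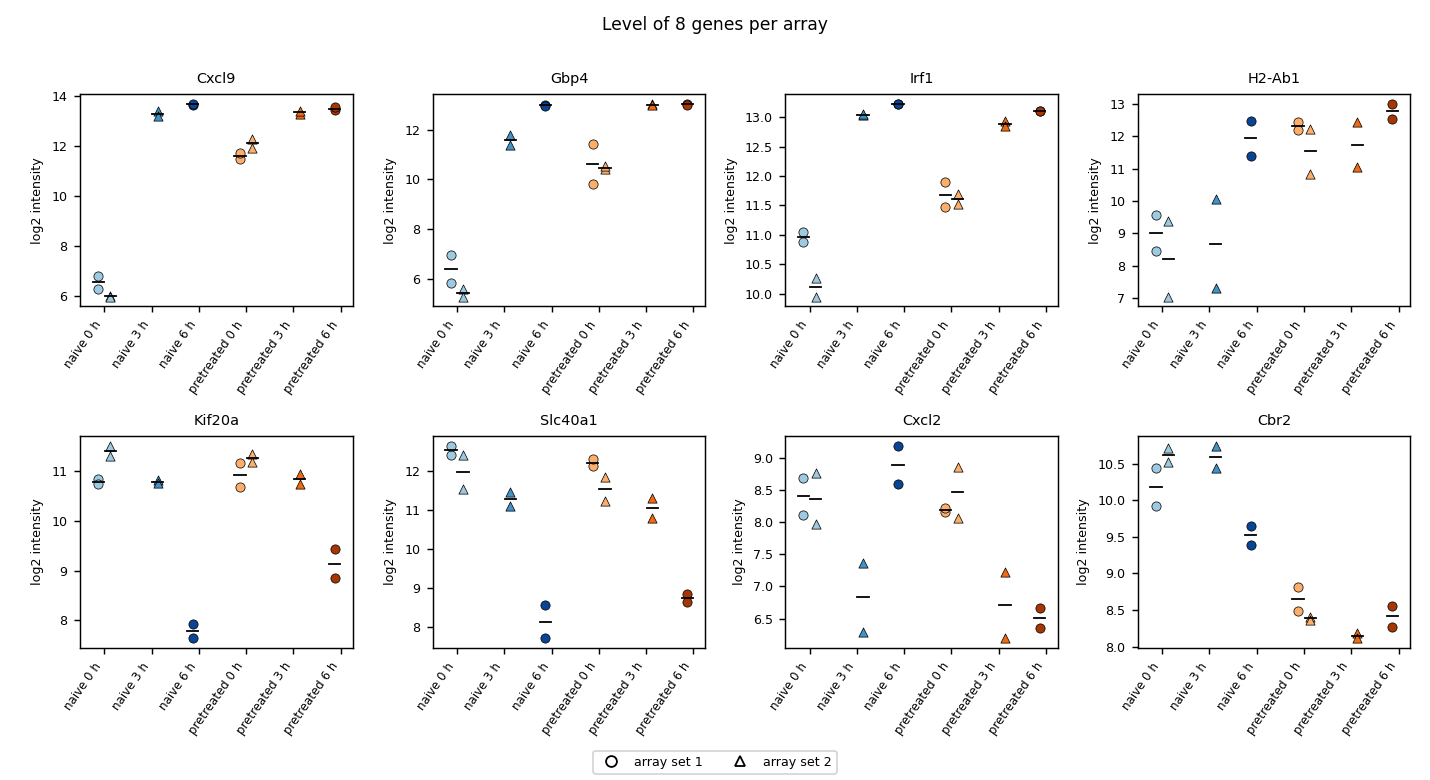
Log2 intensity of 8 genes per array (y axis) by group and time (x axis). Points are arrays, circles set 1 and triangles set 2, bars are the mean of 2 arrays, and Cxcl9 lay at 11.6 and 12.11 on average in pretreated 0 h cells of sets 1 and 2 against 6.55 and 5.99 in naive 0 h cells.

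Markers of other cell types were read beside these groups. None of 15 neutrophil and granulocyte precursor, 14 stromal fibroblast and 10 mast cell and basophil markers passed in any of the 10 comparisons in the limma fit, nor when adjusted over the list alone. Of 13 dendritic cell markers 1 rose in naive cells at 3 h and 4 at 6 h, when Clec9a was at 4.44 ± 0.39, Xcr1 at 1.1 ± 0.28 and Batf3 at 1.04 ± 0.13, and 2 rose in pretreated cells at 6 h, the same counts as adjusted over the list alone. At 0 h Clec9a was 1.67 ± 0.28 higher in pretreated cells. Its naive 0 h levels, 5.55 and 5.04, lay under the dim limit. Of 11 B cell markers Blnk fell by 0.96 ± 0.23 at 3 h in naive cells, by 2.5 ± 0.23 at 6 h in naive and by 1.23 ± 0.23 at 6 h in pretreated cells, and its naive change differed between times by -1.54 ± 0.33. Cd79b fell by 0.58 ± 0.14 at 6 h in naive cells. These B cell counts, 1, 2 and 1 in the responses and 2 for the difference, were the same adjusted over the list alone. Naive 0 h levels in sets 1 and 2 were 11.87 and 11.26 for Blnk and 9.12 and 8.67 for Cd79b. The B cell markers Cd79a (4.92 and 4.89) and Ms4a1 (4.95 and 4.42) lay under the dim limit of 6.5. The falls of Blnk and Cd79b therefore do not show a change in B cells. Of 16 T and NK cell markers Klrd1 rose by 0.53 ± 0.16 at 6 h in naive and by 0.81 ± 0.16 in pretreated cells, the first of which did not pass adjusted over the list alone. All levels of Klrd1 (4.28 to 5.81) lay under the dim limit, so these values do not show that it was expressed. Of 12 erythroid and megakaryocyte markers Epor fell by 0.6 ± 0.16 at 6 h in naive cells and Ppbp was lower at 0 h in pretreated cells (-0.72 ± 0.14, between levels of 5.47 to 6.55, around the dim limit), 1 and 2 adjusted over the list alone.

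Several of these marker calls were lost when 1 array was left out, which also lowers the power of the fit. Blnk lost its call at 3 h without naive 0 h replicate 3 or naive 3 h replicate 2 (adjusted p up to 0.255), at 6 h in pretreated cells without pretreated 0 h replicate 1 or pretreated 6 h replicate 2 (up to 0.062), and for the difference between times for 6 of 8 arrays (up to 0.172, without naive 0 h replicate 4). At 6 h in naive cells Xcr1 lost it without either naive 0 h array or naive 6 h replicate 1 (up to 0.171), Klrd1 without naive 0 h replicate 2 or either naive 6 h array (up to 0.258), and Cd79b and Epor without naive 0 h replicate 2 or naive 6 h replicate 1 (up to 0.118 and 0.206). Klrd1 lost it in pretreated cells without pretreated 0 h replicate 2 or pretreated 6 h replicate 2 (up to 0.103). At 0 h Clec9a lost it without naive replicate 2 or pretreated replicate 4 (up to 0.0544), and Ppbp for 7 of the 8 arrays, all but pretreated replicate 4 (up to 0.105).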

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

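The tests of splits with 2 arrays of each group in each set, of the ceiling in genes that had risen, of whether genes were picked for a high value at 0 h, and of whether the cell cycle difference was already present at 0 h, were chosen only after the result was seen.

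Pretreated and naive cells at 0 h differed in 192 genes. Of 34 splits of the 8 arrays fitted within array sets only the real one gave as many, and the highest other gave 3 (1 of 34). Only 18 of these keep 2 arrays of each group in each set, with 192 in the real one and 3 in the highest other, too few splits for a share under 0.05. The 35th split, by array set, cannot be fitted within sets and calls 13539 genes without a set term. It compares the 2 array sets themselves, whose column medians and minima differ as given above, so it does not bear on pretreatment. The 7 other splits that part all 4 half-sets gave at most 1.

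Genes higher in pretreated cells at 0 h differed less from naive cells after stimulation. Picking genes for a high 0 h value would bring this about, but in genes picked on the other array set the median difference of responses was still -1.1 at 3 h and -0.93 at 6 h. In genes whose stimulated naive level was under 11 the median difference at 6 h was 0.15 times that at 0 h (0.92 to 0.14, 19 of 88 genes). This argues against a ceiling of the array signal for these 19 genes only. A ceiling stays open for genes at 11 or above, among them Cxcl9 (13.67 in naive and 13.5 in pretreated cells at 6 h). At 3 h the median difference in genes under 11 was 0.54 times that at 0 h (1.66 to 0.9, 23 of 45 genes). That decides nothing, since 5 of the 23 had not passed as risen in naive cells and the other 18 gave 0.45 (0.51 and 0.4 in the half-sets), so a ceiling stays open at 3 h. The difference of responses itself was tested (16 and 29 genes, below), and what brought it about was not.

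Of 40 cell cycle genes 6 were higher and none lower in pretreated than in naive cells at 6 h, and the list, past the threshold with a preset correlation, had adjusted p = 0.0603 with an estimated correlation. With 1 of the 4 arrays left out the median difference was at least 0.65, against 0.71 with all, which argues against 1 array out of line. Whether a difference already present at 0 h explains it cannot be told apart: the list had 0.44 at 0 h in set 1 (camera p = 0.0535) and 0.03 in set 2 (p = 0.777), and the difference of 6 h responses had a median of 0.38 (p = 0.199), all with an estimated correlation. A smaller fall in pretreated cells is what that difference of responses measures, and it neither shows nor excludes one.

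Among 63 groups of 4 arrays tested (22 lists and 41 genes), in the pretreated 0 h group, 6 had a sample far from the other 3, and chance gives about 1 in 20. Pretreated 0 h replicate 1 was low for the interferon-inducible GTPases (1.333 above naive 0 h) and Gbp4 (3.41), and Bmp2 (-1.22). Replicate 2 was apart for the TLR and NF-kB list (0.037) and C4b (1.47), and replicate 3 for Cd74 (3.57). Naive 0 h arrays, centred per set, lie evenly around 0 and cannot be tested this way.

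Responses differed between groups, by the test of the difference itself, in 16 genes at 3 h, 29 at 6 h, 345 between naive 6 h and 3 h (time and array set cannot be told apart in these, nor in the pretreated 6 h and 3 h difference), 1 between the 2 sets at 0 h (Ifi205, 2 higher in set 2, adjusted p = 0.0283) and 4 between pretreated 6 h and 3 h. The 4 were Kif18b (-1.33), Nt5dc2 (-1.12), Plac8 (1.68) and Plk1 (-1.6), each with adjusted p = 0.0495, and these 5 genes were named after their values were seen.

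For pretreated minus naive at 3 h the difference was -6.07 for Cxcl9, -4.48 for Iigp1, -2.77 for Ifi205, -2.76 for Acod1, -2.61 for Zbp1, -2.3 for Gbp3, -1.94 for Fcgr4, -1.82 for Ifit2, -1.65 for Irf1, -1.47 for Tap1 and for Nlrc5, -1.32 for Tapbpl and -1.09 for Psmb9. At 6 h it was -5.22 for Cxcl9, -4.16 for Gbp4, -3.78 for Iigp1, -2.77 for Acod1, -2.55 for Cfb, -2.53 for Slamf8, -2.47 for Rasgrp1, -2.07 for C1s1, -1.74 for Zbp1, -1.38 for Tap1, 1.43 for Ptger1, 1.3 for Havcr2 and 1.14 for Lpxn.

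For naive 6 h minus 3 h it was 4.6 for Ak4, 3.53 for Clec9a, 2.46 for Mthfd2 and for Procr, 2.43 for Upp1 and for Clec5a, 2.37 for Flt1, 2.28 for Cfb, 1.83 for Il12rb1, 1.73 for C1s1, 1.58 for Il27, 1.35 for Hsp90aa1, 1.15 for Dnajb1, 1 for C1ra and 0.93 for Psmb8. It was -3.69 for Slc40a1, -2.69 for Ednrb, -2.66 for Arhgap19, -2.57 for Ahr, -2.4 for Kif20a, -2.32 for Ccna2, -2.31 for Nusap1, -1.54 for Blnk, -1.46 for Asf1b and -1.38 for Cish.

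Among the 1621 features with several gene symbols, outside the comparisons, 51 were higher in naive cells at 3 h, 72 at 6 h and 31 in pretreated cells at 0 h, against 4, 63 and 0 lower.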

How the results depend on the processing

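Array weights were chosen after seeing the data. With 2 arrays per cell the weights came out equal within a cell (0.59 to 1.48), so they weight cells and not arrays. Of 299 gene and comparison values in the text 253 passed, 153 of them under every setting and 100 lost the call under at least 1, 83 when 1 array was left out and 66 without the array-set term, and none changed direction while called. The cause of these changes was not tested. The spread between 2 arrays limits every comparison. The named genes past the threshold kept their direction in each setting run.

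In the order naive 3 h (1088 genes), naive 6 h (3653), pretreated 3 h (569), pretreated 6 h (1126), pretreated against naive at 0 h (192), 3 h (3) and 6 h (140), the differences of responses at 3 h (16) and 6 h (29) and of naive responses (345), counts moved by over 1.5 times as follows. The 2-fold limit, which by construction lowers counts, left 487, 1310, 250, 466 and 85 in the first 5 and 67 at 6 h. An additive array-set term gave 923 in pretreated cells at 3 h, 273 at 6 h between groups, and 10, 245 and 1088 for the differences. Without an array-set term they were 100 at 0 h, 1 at 3 h, 9 at 6 h, and 2, 13 and 1288 for the differences, a fit that shifts the median of all genes by -0.178 for naive 3 h, 0.182 for naive 6 h and 0.331 for the naive difference. There the share of higher calls was 52.3% against 40.8% for naive 6 h, 51.1% against 65% for pretreated 3 h, 97% against 83.9% at 0 h, 0% against 66.7% at 3 h and 22.2% against 61.4% at 6 h between groups, 0% against 20.7% for the 6 h difference and 66.8% against 39.4% for the naive one. With the additive term it was 50% at 3 h between groups and 37.6% for the 6 h difference. Each array set alone gave 29 at 6 h between groups, and 8 and 14 for the differences at 3 h and 6 h. All features gave 1 at 3 h and 54 at 6 h between groups, and 26, 47 and 204 for the differences. Array weights gave 245 in pretreated cells at 3 h, 1 at 3 h and 572 at 6 h between groups and 751 for the naive difference.

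With 1 array left out the counts were 543 to 716, 2217 to 2981, 219 to 429, 486 to 861, 142 to 203, 1 to 2, 13 to 406, 8 to 14, 4 to 157 and 63 to 447. The arrays behind the moves of over 1.5 times are named with each comparison above.

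The half-sets as a replicate block (positions 1 to 4 and 5 to 8 of a set) gave 2390 in naive cells at 3 h, 1882 and 2331 in pretreated cells at 3 h and 6 h, 768 at 0 h, 88 at 3 h and 1098 at 6 h between groups, and 1095 and 2376 for the differences at 6 h and of naive responses. Deviations of arrays in the same half-set correlated at over 0.1 in 11 of 12 pairs of groups, with a lowest of 0.082 and a highest of 0.662. The second principal component was higher in the first half-set in all 8 groups within sets. The titles also place 1 array of each group of a set in each half-set, but the labels do not say what a half-set shares. If half-sets are replicates, the main fit counts the spread between them as error. Of 220 list tests 96 passed with a preset and 35 with an estimated correlation. In genes picked on the other array set, the pretreated minus naive median at 3 h (0.012) was 0.009 without dim features, 0.033 after quantile normalization and -0.044 to 0.064 with 1 array left out, and the other 3 medians kept their sign, with -0.225 to -0.055, -0.218 to -0.165 and -0.543 to -0.369.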

Other observations

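The tests on symbol families, on features without a single symbol and on genes with a small 0 h contrast were chosen only after the results were seen. Genes were grouped by the letters that start their symbol, which gave 249 families of at least 10 measured members and 996 tests over 4 comparisons. The Ifi family, of interferon-induced genes, had 7 of 15 members that rose and none that fell in naive cells at 3 h (median log2 change 1.11, adjusted p = 4.75e-10). The Parp family, of ADP-ribosyltransferases, had 6 of 11 that rose and 1 that fell (median 1.09, adjusted p = 7.45e-06). At 0 h 6 Ifi, 5 Parp and 3 of 11 Psmb genes, which encode proteasome subunits, were higher in pretreated cells. With an estimated correlation each of these family tests had adjusted p = 0.995, so none held.

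In naive cells at 6 h the Kif family, of kinesins, had 17 of 38 members that fell and 4 that rose (adjusted p = 0.00222), the Mcm family 4 of 10 that fell (median -0.8, adjusted p = 0.0098), and the Ift family, of intraflagellar transport, 5 of 14 that fell. The Srsf family, of splicing factors, had 5 of 10 that rose (median 0.44, adjusted p = 0.00664) and the Hspa family 4 of 12. In pretreated against naive cells at 6 h the median was 0.59 for Mcm (adjusted p = 6.22e-05), -0.29 for Srsf (adjusted p = 0.00106) and -0.22 for Hspa (adjusted p = 0.00423). These too had adjusted p = 0.995 with an estimated correlation.

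Of 12147 features without a symbol 245 rose and 42 fell in naive cells at 3 h, 516 rose and 249 fell at 6 h, and 35 were higher and 22 lower in pretreated cells at 0 h.

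Genes that rose in naive cells without a difference left by pretreatment were read on the other array set, again picked in naive cells only. The 342 genes that rose in naive cells at 3 h with a 0 h contrast under 0.25 in size in set 2 had a median of -0.2 for pretreated against naive cells at 6 h (camera p = 2.62e-26, p = 0.000269 with an estimated correlation). The 958 genes that rose at 6 h with a 0 h contrast under 0.25 in size in set 1 had -0.02 at 3 h (camera p = 0.0317, p = 0.59 with an estimated correlation).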
